A study of Arabidopsis thaliana with 8 samples.

How the data were processed

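Transcripts were measured in 8 libraries from whole Arabidopsis thaliana seedlings of the accession Landsberg erecta, 14 days old. The 4 groups were wild type (WT) and the homozygous smn2 mutant, each treated with 0.1 µM flg22, the peptide of bacterial flagellin that plants perceive, for 0 h or 4 h, with 2 biological replicates per group. SMN2 is the gene HEN2, which encodes a helicase of the nuclear RNA exosome, and SMN1, found in the same line of work, is the immune receptor gene RPS6; both identities are background knowledge and not from the labels. Per the labels' protocols, total RNA was extracted with a NucleoSpin plant kit, poly(A) RNA was purified on Dynabeads and libraries were made with an Ion Total RNA-Seq kit. Samples were grouped by genotype and time from their titles. The titles also carry the numbers 910 and 918, used as replicate numbers. No mock-treated group at 4 h was analysed here, so the 4 h changes combine flg22 with time of day and handling.

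One table of 28642 loci was used. It holds, per the file headers, a read count per locus and library for genes, exons and introns, each as total reads and as uniquely placed reads. The total gene counts deposited by the authors were not normalized and equal exon plus intron counts at every locus. At 1314 loci, nearly all non-coding, the table gives no exon length and places every read outside exons. The RPKM values deposited by the authors are exon reads per kilobase of exon and per 1000000 mapped reads, and served only to recover the number of mapped reads. The authors' own p-values and FDR values come, per the file headers, from pairwise EDGE tests with tagwise dispersions, whose settings are not stated. The fold changes deposited by the authors are signed linear values. The submitters' processing notes name TAIR10 as the genome build; the aligner, the annotation release and whether counting used strand are not given in the sources used here. Reads of overlapping genes and of a gene and its antisense partner can therefore not be told apart. Any sequence difference between Landsberg erecta and that build was not taken into account in the tests here. Positions are those of the authors' table, with starts shifted so that they count from 1. Symbols and gene classes came from the reference gene table, which matched 27997 of the 28642 loci.

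Total gene counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr, which kept 19649 loci. All 8 libraries entered 1 fit with a coefficient per group and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. The 6 comparisons were the 4 h change in WT, the 4 h change in smn2, smn2 against WT at 0 h and at 4 h, the difference of the 4 h changes (interaction), and the mean of the genotype effects at both times. CPM values are per 1000000 TMM-scaled gene reads, and every mean ± SD is over 2 libraries. Libraries held 6856882 to 15791296 gene reads, at which 3 counts correspond to 0.161 to 0.488 CPM. A fold against a group with 0 reads was taken against a floor of 3 counts over the group and is written as a lower bound. Floors and counting intervals cover counting error only, because reads are not independent molecules. Other intervals, given in brackets after the medians of sets of genes, are 95% bootstrap intervals that resample genes with the libraries held fixed. They do not measure the spread between replicates, and genes are not independent of each other. The adjusted p-values use the spread between these biological replicates, pooled over all groups.

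The 21 gene lists comprised flg22 markers, pattern recognition receptors and kinases, MAP kinases and their guards, salicylic acid, NLR immune receptors, the RPS6 gene cluster, RNA exosome and decay, camalexin and indole glucosinolates, jasmonate, ethylene, light harvesting and Rubisco, auxin, circadian clock, heat shock, root markers, vascular and guard cell markers, snRNA, snoRNA, lncRNA, other ncRNA and pseudogenes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, and adjusted over all 126 list tests. Camera compares a list with all other genes. With an estimated correlation it called none of the 126 list tests, not even the flg22 markers at 4 h. A call missing in that setting therefore cannot decide whether a list changed. The fry p-value tests whether a list's genes move, on balance, one way, and its mixed p-value whether they change in either direction; neither compares the list with other genes. Camera lists share few members: 1 between camalexin and flg22, 1 between MAP kinases and NLR, and 3 between NLR and the RPS6 cluster. The called share of genes was compared between windows of 1000000 bp by Fisher's exact test. Named genes followed a rule: HEN2 and RPS6 always; per comparison the 8 largest increases and 8 largest decreases among genes past the threshold with a mean count of at least 20 and no overlap of the groups; and the 3 members of each list with the lowest p. Genes outside it are said to be chosen after their values were seen.

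The share of reads outside exons was tested with limma on the log2 ratio of intron to exon reads with a pseudocount of 0.5, centred per library, for the 2762 genes with a mean of at least 10 reads of each kind. This comparison, which takes up the degraded regions named in the series title, was chosen after the data were seen.

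The edgeR fit was tested on simulated data, negative binomial counts drawn from each gene's mean and dispersion and the real library sizes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. At log2 2 the edgeR test recovered 63% of changed genes for the WT 4 h change (19312 genes run), 73% for the smn2 4 h change (19162), 84% for genotype at 0 h (19258), 77% for genotype at 4 h (19315), 25% for the difference of changes (19232) and 93% for the mean genotype effect (19407). At log2 1 the same comparisons gave 5%, 10%, 5%, 12%, 1% and 44%. Over genes of both sizes, false calls were 6 of 74, 6 of 89, 7 of 96, 7 of 96, 7 of 33 and 8 of 145 calls, in the same order. For the mean genotype effect, the intron test run on simulated ratios recovered 75% at log2 2 and 3.03% at log2 1 among 2576 genes. With no list moved, camera called 1 of 126 list tests. The simulated genes were drawn independently of each other, so this does not measure false calls for lists whose genes vary together.

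The numbers 910 and 918 name different Ion Proton runs in the file headers and so link libraries of different groups. The run was not in the edgeR fit, and entered only as the replicate block, an alternative. As a check, deviations of the 910 libraries from their group means were correlated between groups: r across genes was 0.452 between WT and smn2 at 0 h and 0.0477 to 0.135 for the other pairs of groups. The 2 replicates of a group were not copies of 1 library: their counts differed by a chi-square of 27.6 to 75.1 per gene, with correlations of log2 CPM of 0.946 to 0.964.

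The comparisons, tests, lists, gene rule and the following alternatives were fixed before the data were examined: DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, a mean count of at least 20, fitting only the 4 libraries compared, the replicate block, a test against a fold of 1.5 (glmTreat), uniquely placed reads and leaving out each library. Exon reads, a fit without ribosomal and mitochondrial genes, leave-outs for the list, agreement and window results, and the alternatives for windows and intron shares were added after the data were seen. Where a leave-out keeps 1 library in a group, that library is assumed to vary like the other groups. Tables and figures were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.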

Results

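Poly(A)-selected RNA of whole seedlings was counted in 8 Ion Proton libraries, 2 biological replicates each of WT and smn2 at 0 h and 4 h of flg22. The libraries of replicate 910 held 15791296 gene reads (WT, 0 h), 9729245 (WT, 4 h), 9893488 (smn2, 0 h) and 8371963 (smn2, 4 h). Those of replicate 918 held 10926158, 8635658, 7423140 and 6856882 in the same order. Reads fell on 22531 to 24808 loci per library. Ribosomal RNA loci took 26.7% to 35.8% of gene reads in the 910 libraries and 40.3% to 44.4% in the 918 libraries, which were sequenced in different runs. The first principal component of log2 CPM (57.7% of the variance) separated the times, the second (14.0%) the genotypes and the third (9.76%) the runs. The common biological coefficient of variation was 0.229, and the median log2 change of all 19649 tested loci lay between -0.0374 and -0.00409 in every comparison.

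The mutated gene was examined first. HEN2 (chromosome 2, 2894940 to 2901078, TAIR10), a helicase that feeds nuclear RNA to the exosome for degradation, had 34.7 and 32 CPM in WT at 0 h and 55.7 and 50 CPM at 4 h. In smn2 it had 10.6 and 9.71 CPM at 0 h and 11.9 and 15.1 CPM at 4 h. HEN2 was lower in smn2, with a log2 value (± SE) of -1.71 ± 0.20 at 0 h (edgeR adjusted p = 0.00679) and -1.97 ± 0.20 at 4 h (adjusted p = 0.00481). The labels do not state where in the gene the lesion lies, so the remaining reads say nothing about the protein. RPS6 (chromosome 5, 18842701 to 18849741), which encodes a TIR-NLR immune receptor, showed no detected difference: its mean genotype log2 value was 0.31 ± 0.19 (adjusted p = 0.557). HEN2 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0656). HEN2 lost its edgeR call at 4 h without WT 4 h 910 (adjusted p = 0.0652), WT 4 h 918 (0.0531) or smn2 4 h 910 (0.123).

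**Figure D1:**
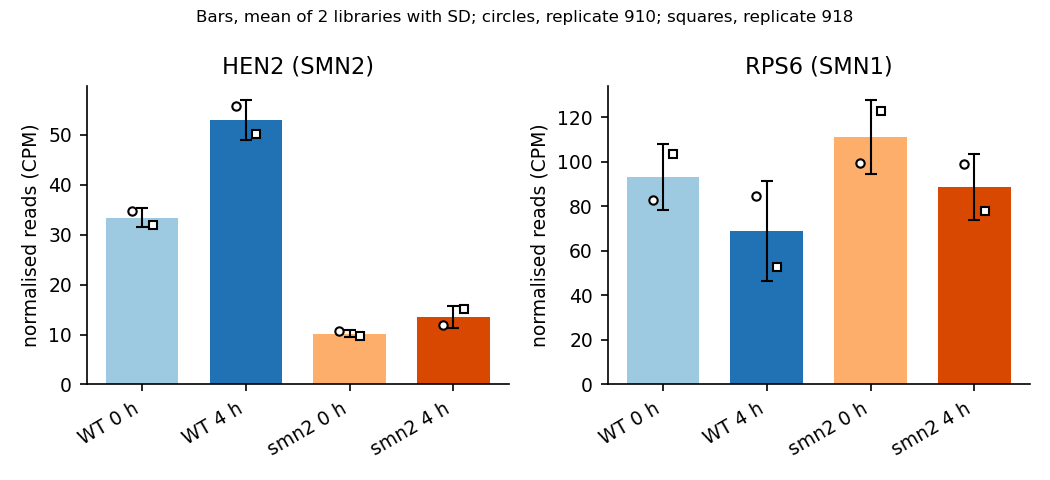
Mean CPM of HEN2 and RPS6 in each group (bars, SD of 2 libraries), with the 910 library as a circle and the 918 library as a square. HEN2 lay at 33.3 and 52.9 CPM in WT and at 10.2 and 13.5 CPM in smn2, at 0 h and 4 h.

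The first comparison was the response of WT to 4 h of flg22. FRK1, a receptor-like kinase gene used as a flg22 marker, rose from 1.59 ± 0.270 to 169 ± 41.5 CPM (mean ± SD, n = 2), a log2 change of 6.75 ± 0.45. PROPEP3, which encodes the precursor of a danger peptide, rose by 5.52 ± 0.27. Genes of tryptophan-derived defence compounds rose with them, among them CYP79B2 (3.87 ± 0.42) and CYP83B1 (2.91 ± 0.32). GolS2, a galactinol synthase gene, fell by a log2 of 6.27 from 18.9 ± 2.14 to 0.223 ± 0.129 CPM. CYP79B2 had a log2 value of 3.12 without WT 4 h 910. GolS2 had a log2 value of -7.05 without WT 4 h 910.

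Among the fixed lists, 21 of 30 flg22 markers rose and 9 did not pass (24 rose adjusted over the list alone, median log2 1.97, camera adjusted p = 6.17e-15, adjusted p = 0.544 with an estimated correlation). Of 12 pattern recognition receptor and kinase genes 9 rose, including the flagellin receptor FLS2 (1.81 ± 0.27), the chitin receptor kinase CERK1 (1.38 ± 0.20) and the cytoplasmic kinase BIK1 (1.92 ± 0.29), and 9 rose adjusted over the list alone (median 1.27, camera adjusted p = 2.03e-05, adjusted p = 0.575 with an estimated correlation). Of 20 camalexin and indole glucosinolate genes 17 rose (18 rose and 1 fell adjusted over the list alone, median 2.49, camera adjusted p = 1.81e-12, adjusted p = 0.547 with an estimated correlation). Of 18 genes of MAP kinase cascades and their guards 3 rose, MPK11, MPK4 and MKK4, also adjusted over the list alone (median 0.35, camera adjusted p = 0.0433, adjusted p = 0.588 with an estimated correlation). Ethylene genes rose in 8 of 15 cases and 1 fell, with ACO1 (2.26 ± 0.30) and ACS6 (1.87 ± 0.33) among the enzymes of ethylene synthesis that rose (9 rose and 2 fell adjusted over the list alone, median 0.82, camera adjusted p = 0.00620, adjusted p = 0.588 with an estimated correlation). Exosome and RNA decay genes rose in 6 of 30 cases, led by AT5G38890 (1.75 ± 0.39), and 11 rose adjusted over the list alone (DESeq2 2, median 0.46, camera adjusted p = 0.00334, adjusted p = 0.544 with an estimated correlation). MPK4 lost its edgeR call without WT 0 h 918 (adjusted p = 0.0561) or WT 4 h 910 (0.0656). MKK4 lost its edgeR call without WT 0 h 910 (adjusted p = 0.127) or WT 4 h 918 (0.120), and against a fold of 1.5 (0.0719). AT5G38890 lost its edgeR call without WT 0 h 910 (adjusted p = 0.108), WT 4 h 910 (0.0633) or WT 4 h 918 (0.0705). MAP kinases lost the camera call without WT 0 h 910 (adjusted p = 0.225) or WT 4 h 910 (0.15).

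Other lists had lower medians at 4 h. Of 19 auxin genes 7 fell and 1 rose (9 fell and 1 rose adjusted over the list alone, median -1.21, camera adjusted p = 0.000254, adjusted p = 0.547 with an estimated correlation). The members that fell included DFL1 (-2.04 ± 0.25) and WES1 (-2 ± 0.23), while BRU6 (1.82 ± 0.32) rose; all 3 encode enzymes that join auxin to amino acids. Light harvesting and Rubisco genes had a median of -1.16 over 24 genes (camera adjusted p = 1.82e-05, adjusted p = 0.628 with an estimated correlation). By edgeR LHCB4.2 fell and RBCS1B rose, also adjusted over the list alone, while 13 members were lower at unadjusted p under 0.05 and DESeq2 called 6 lower and 1 higher. LHCB4.2 overlaps another gene, and 70.8% of RBCS1B reads were uniquely placed. Root markers had a median of -0.89 over 19 genes, of which 3 fell, also adjusted over the list alone (camera adjusted p = 0.00861, adjusted p = 0.589 with an estimated correlation). LHCB4.2 lost its edgeR call without WT 0 h 910 (adjusted p = 0.0506), WT 0 h 918 (0.0863) or WT 4 h 918 (0.0718), and against a fold of 1.5 (0.0621). RBCS1B lost its edgeR call without WT 0 h 910 (adjusted p = 0.143) or WT 4 h 918 (0.158), and against a fold of 1.5 (0.0792). Root markers lost the camera call without WT 4 h 910 (adjusted p = 0.0639). LHCB4.2 had a log2 value of -3.09 without WT 4 h 910 and -1.31 without WT 4 h 918.

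The remaining lists were not called by camera in WT. Jasmonate genes rose in 5 of 21 cases and fell in 3, with JAZ1 at 2.82 ± 0.28 (7 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.0618). Heat shock genes rose in 6 of 13 cases and 1 fell, with BIP3, a chaperone gene of the endoplasmic reticulum, at 3.80 ± 0.80 (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0507, and 0.0115 with the run as a block, which is called). Salicylic acid genes rose in 3 of 31 cases and fell in 2, with GRX480 at 3.38 ± 0.44 and DMR6 at -1.70 ± 0.28, also adjusted over the list alone (camera adjusted p = 0.810). NLR genes rose in 2 of 28 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.333). Clock genes fell in 2 of 21 cases and in 0 adjusted over the list alone by edgeR, with 7 at unadjusted p under 0.05 and 4 lower by DESeq2 (camera adjusted p = 0.588). No member passed by edgeR or by DESeq2 in 5 lists: vascular and guard cell markers (3 at unadjusted p under 0.05, camera adjusted p = 0.212), the RPS6 cluster (1, 0.761), snRNA (0, 0.723), snoRNA (1, 0.607) and pseudogenes (1, 0.620). Of 103 lncRNA genes 3 rose and 4 fell, and 0 passed adjusted over the list alone by edgeR, with 22 at unadjusted p under 0.05 and 5 called by DESeq2 (camera adjusted p = 0.943). Of 77 other ncRNA genes 1 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.342). BIP3 lost its edgeR call without WT 0 h 910 (adjusted p = 0.0767) or WT 0 h 918 (0.0545). BIP3 had a log2 value of 1.53 without WT 4 h 910 and 4.63 without WT 4 h 918.

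In all, edgeR called 1989 loci higher and 1289 lower at 4 h in WT, of which 1510 and 1021 changed at least 2-fold. Among the largest increases were AT5G48430 (9.92 ± 0.57) and DIN11 (8.41 ± 0.80), and CYP710A3 was at least 77.9-fold higher against 0 reads at 0 h. ABR1, which overlaps another gene, had a ratio of 254 (counting interval 86.4 to 1236). CYP82F1 was at least 53.7-fold lower, and AT5G37990 (-5.84 ± 0.64) and NUDT24 (-5.04 ± 1.01) fell. Without 1 WT library the counts were 884 higher and 494 lower (0 h, 910), 1252 and 839 (0 h, 918), 1107 and 593 (4 h, 910) and 1103 and 468 (4 h, 918). HEN2 rose in WT (0.66 ± 0.19, adjusted p = 0.0425 by edgeR and 0.104 by DESeq2), its smn2 value was 0.40 ± 0.21 (adjusted p = 0.208), and the difference was -0.26 ± 0.28. Against a fold of 1.5, 993 and 544 loci passed, and without the low-count filter 2117 were lower. NUDT24 lost its edgeR call without WT 4 h 910 (adjusted p = 0.0840) or WT 4 h 918 (0.0639). HEN2 lost its edgeR call without the low-count filter (adjusted p = 0.0552), the other 4 libraries (0.0543), intron reads (0.0621), WT 0 h 910 (0.139), WT 0 h 918 (0.170), WT 4 h 910 (0.197), WT 4 h 918 (0.108), smn2 4 h 910 (0.0529) or smn2 4 h 918 (0.0538), and against a fold of 1.5 (0.533). DIN11 had a log2 value of 9.96 with exon reads alone, 7.69 without WT 0 h 910, 9.11 without WT 0 h 918 and 7.67 without WT 4 h 910. NUDT24 had a log2 value of -3.06 without WT 0 h 910 and -5.82 without WT 0 h 918.

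The same comparison in smn2 asked whether the mutant responds. FRK1 rose from 0.361 ± 0.0817 to 244 ± 128 CPM (n = 2), a log2 change of 9.30 ± 0.55, and PROPEP3 rose by 7.33 ± 0.31. In the smn2 0 h libraries 3 counts correspond to 0.251 CPM (910) and 0.455 CPM (918). The size of the FRK1 change therefore rests on few reads at 0 h. MPK11, a MAP kinase gene, rose by 3.79 ± 0.41, and CBP60G, a transcription factor gene of salicylic acid synthesis, by 3.96 ± 0.41. JAZ8, a repressor of jasmonate signalling, was at least 18.1-fold higher against 0 reads at 0 h. GolS2 fell by a log2 of 5.80 and BXL1, a gene of cell wall xylan turnover, by 4.50 (n = 2 against 2, both past the edgeR threshold). FRK1 had a log2 value of 8.63 without smn2 4 h 910. GolS2 had a log2 value of -5.06 without smn2 4 h 918. GolS2 had 0 reads left in smn2 at 4 h without smn2 4 h 910, so its size there is not given.

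Of 30 flg22 markers 24 rose (26 adjusted over the list alone, median 3.23, camera adjusted p = 5.76e-15, adjusted p = 0.544 with an estimated correlation). Of 12 receptor and kinase genes 9 rose, also adjusted over the list alone, with FLS2 at 2.23 ± 0.27 and CERK1 at 2.18 ± 0.21 (median 1.4, camera adjusted p = 6.1e-07, adjusted p = 0.547 with an estimated correlation). Of 20 camalexin and indole glucosinolate genes 18 rose and 1 fell (19 and 1 adjusted over the list alone, median 3.54, camera adjusted p = 5.21e-14, adjusted p = 0.544 with an estimated correlation). Of 18 genes of MAP kinase cascades and their guards 5 rose (6 adjusted over the list alone, median 0.50, camera adjusted p = 0.00915, adjusted p = 0.547 with an estimated correlation). Of 31 salicylic acid genes 11 rose and 1 fell (12 and 2 adjusted over the list alone, median 1.13, camera adjusted p = 0.00438, adjusted p = 0.670 with an estimated correlation). Of 21 jasmonate genes 9 rose (DESeq2 10 higher and 2 lower, 11 rose and 3 fell adjusted over the list alone), with ORA59 at 2.67 ± 0.22 and a median of 1.19 that stayed at 1.19 with zero-read members at their bound (camera adjusted p = 0.00230, adjusted p = 0.588 with an estimated correlation). Of 15 ethylene genes 9 rose and 1 fell, also adjusted over the list alone (median 0.85, camera adjusted p = 0.00461, adjusted p = 0.547 with an estimated correlation). Of 30 exosome and decay genes 4 rose, RRP4 (1.46 ± 0.43) among them, and 0 adjusted over the list alone by edgeR, where 9 were under an unadjusted p of 0.05 and DESeq2 called 2 (median 0.43, camera adjusted p = 0.0300, adjusted p = 0.544 with an estimated correlation). RRP4 lost its edgeR call without WT 4 h 910 (adjusted p = 0.0509), smn2 0 h 910 (0.0517), smn2 0 h 918 (0.139), smn2 4 h 910 (0.0600) or smn2 4 h 918 (0.2), and against a fold of 1.5 (0.116). MAP kinases lost the camera call without smn2 0 h 910 (adjusted p = 0.0672). Exosome and decay genes lost the camera call without smn2 0 h 910 (adjusted p = 0.0664) or smn2 4 h 910 (0.0582).

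Of 24 light harvesting and Rubisco genes 2 fell and RBCS1B rose by edgeR (DESeq2 6 lower and 1 higher, 9 fell and 1 rose adjusted over the list alone, median -1.28, camera adjusted p = 2.03e-05, adjusted p = 0.628 with an estimated correlation). Of 19 auxin genes 6 fell and 1 rose, DFL1 at -2.50 ± 0.25 and BRU6 at 3.04 ± 0.34 (8 and 2 adjusted over the list alone, median -1.53, camera adjusted p = 0.00826, adjusted p = 0.588 with an estimated correlation). The other lists were not called by camera. NLR genes rose in 6 of 28 cases, RPM1 at 1.26 ± 0.25, and fell in 3, also adjusted over the list alone (camera adjusted p = 1). Clock genes fell in 3 of 21 cases, also adjusted over the list alone (0.682). Heat shock genes rose in 2 of 13 cases and fell in 2, also adjusted over the list alone (0.988), with BIP3 at 6.13 ± 0.95. Among 19 root markers SULTR1;2 rose (1.35 ± 0.25) and 1 fell, 1 and 0 adjusted over the list alone (camera adjusted p = 0.551, median -0.38, also with zero-read members at their bound). AT5G46450 rose among 7 genes of the RPS6 cluster (0 adjusted over the list alone by edgeR, 1 at unadjusted p under 0.05, DESeq2 0, 0.943). Pseudogenes fell in 1 of 4 cases, also adjusted over the list alone (0.521). LncRNA genes rose in 5 of 103 cases and fell in 5 (4 and 3 adjusted over the list alone, 0.854), and other ncRNA genes in 3 and 4 of 77 (2 and 2, 0.574). No vascular marker (3 at unadjusted p under 0.05, camera adjusted p = 0.105), snRNA (0, adjusted p = 1) or snoRNA (4, 0.111, and 0.0293 with the run as a block, which is called) passed by edgeR or by DESeq2. RBCS1B lost its edgeR call without smn2 0 h 918 (adjusted p = 0.130), smn2 4 h 910 (0.0542) or smn2 4 h 918 (0.174), and against a fold of 1.5 (0.109). RPM1 lost its edgeR call without smn2 4 h 910 (adjusted p = 0.0521). AT5G46450 lost its edgeR call without the other 4 libraries (adjusted p = 0.0933), WT 0 h 910 (0.0646), WT 0 h 918 (0.0640), WT 4 h 910 (0.0667), WT 4 h 918 (0.0620), smn2 0 h 910 (0.222), smn2 4 h 910 (0.228) or smn2 4 h 918 (0.0837), with DESeq2 size factors (0.0503), and against a fold of 1.5 (0.508).

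In smn2, 2478 loci were higher and 1745 lower at 4 h, 1887 and 1288 of them at least 2-fold. Among the largest were AT5G48430 (10.25 ± 0.60), ELI3-2 (at least 73.6-fold higher), CCOAMT (at least 79.6-fold higher) and AT3G27250 (-5.01 ± 0.54). Without 1 smn2 4 h library the counts were 1469 and 726 (910) or 1515 and 600 (918), and against a fold of 1.5 they were 1388 and 680. AT5G48430 had a log2 value of 9.59 without smn2 0 h 918. AT5G48430 had 0 reads left in smn2 at 0 h without smn2 0 h 910, so its size there is not given.

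Across the 19649 loci the 4 h changes of both genotypes, which share no library, correlated with r = 0.821 (Spearman rho 0.773, slope 0.927), across genes that are not independent replicates. Of the loci called in each, 1615 rose in both (251 for independent lists), 901 fell in both (114) and 1 went opposite ways, and 99.1% of the loci called in WT had the same sign in smn2. Without 1 library r was 0.730 (WT 0 h, 910), 0.774 (WT 0 h, 918), 0.699 (WT 4 h, 910), 0.746 (WT 4 h, 918), 0.667 (smn2 0 h, 910), 0.766 (smn2 0 h, 918), 0.721 (smn2 4 h, 910) and 0.751 (smn2 4 h, 918).

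**Figure D2:**
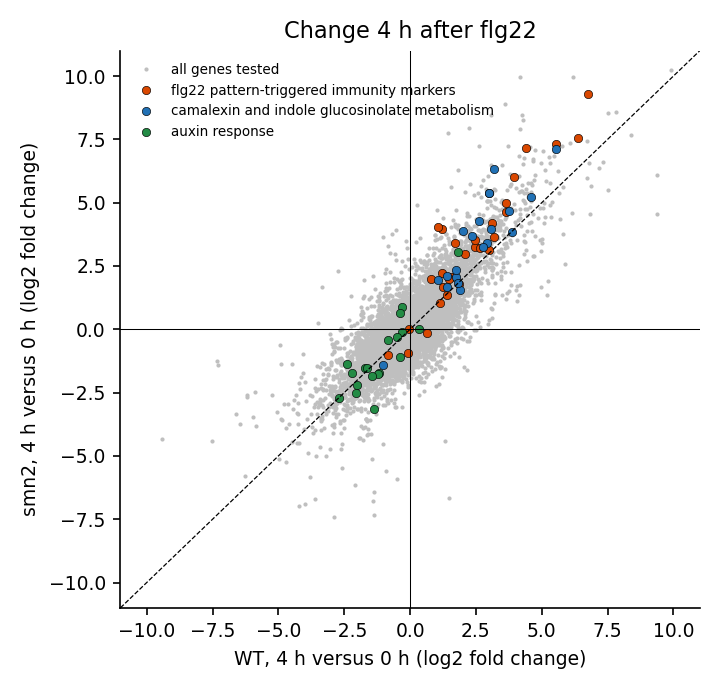
Log2 change at 4 h in WT (x axis) against smn2 (y axis) for the tested loci, with flg22, camalexin and auxin list members coloured; loci with 0 reads in a group are drawn at their fitted value. The changes correlated with r = 0.821 across genes.

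Whether the 4 h change depends on genotype was tested as the difference of the changes. By edgeR none of the genes named here passed: PER4, a peroxidase gene, had a difference of 2.08 ± 0.47 (smn2 minus WT), PROPEP3 of 1.81 ± 0.45 and FRK1 of 2.55 ± 0.73. BGL2 (PR2), a beta-glucanase gene induced by salicylic acid, had 3.17 ± 0.69 and CYP71A12, a camalexin gene, 3.12 ± 0.72. By DESeq2 PER4 (adjusted p = 0.0248), CYP71A12 (0.00270) and BGL2 (0.00370) passed, as did these and FRK1 by edgeR without the low-count filter (1.31e-12 to 0.00145). Over all loci edgeR called 0 higher and 0 lower (847 at unadjusted p under 0.05, lowest adjusted p = 0.641), and DESeq2 called 25 and 3. Without the low-count filter 148 and 37 loci passed. The lowest adjusted p over all loci was then 1.06e-12 by edgeR, against 0.641 with the filter. Calls of the unfiltered fit therefore depend on the filter and are not taken as support for a difference. As lists, salicylic acid, flg22, camalexin, jasmonate, receptor and kinase, and root marker genes differed upwards and snoRNA and heat shock genes downwards by camera, each lost with an estimated correlation, where the lowest adjusted p was 0.544. Since that setting called none of the 126 list tests, it cannot decide these differences. The other lists did not differ by camera: MAP kinases (adjusted p = 0.140), NLR (0.101), RPS6 cluster (0.864), exosome (0.319), ethylene (0.761) and light harvesting (0.864). Nor did auxin (0.634), clock (0.673), vascular (0.552), snRNA (0.337), lncRNA (0.947), other ncRNA (1) or pseudogenes (0.699). PER4 had a log2 difference of 1.45 without WT 0 h 918. FRK1 had a log2 difference of 1.88 without smn2 4 h 910, and its difference rests on few reads in smn2 at 0 h. BGL2 had a log2 difference of 4.09 without WT 4 h 910. CYP71A12 had a log2 difference of 2.51 without WT 0 h 918, 3.98 without WT 4 h 910 and 3.83 without smn2 0 h 910.

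Before treatment, the comparison of smn2 with WT asked which transcripts depend on SMN2. Of the genes called, 5 of 31 in the salicylic acid list were lower in smn2 at 0 h, a list with an adjusted p = 0.544 with an estimated correlation. ACD6, a membrane protein gene that promotes salicylic acid accumulation, fell from 17.1 ± 5.24 to 2.70 ± 0.809 CPM (n = 2), a log2 value of -2.61 ± 0.36. FMO1, an enzyme gene of systemic resistance, was lower, at -2.92 ± 0.45, as was the transcription factor gene WRKY54, at -2.78 ± 0.46. PCC1 (-4.23 ± 0.62), ECS1 (-4.16 ± 0.44) and BGL2 (-3.01 ± 0.51) were among the largest decreases. AT1G34400 rose from 0.206 ± 0.0122 to 36.6 ± 2.86 CPM, a log2 value of 7.37 ± 0.50, or 5.05 with exon reads alone. ACD6 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0830) or WT 0 h 918 (0.0897). FMO1 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0943), WT 0 h 918 (0.126) or smn2 0 h 918 (0.0623). WRKY54 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.165), WT 0 h 910 (0.0607), WT 0 h 918 (0.147), WT 4 h 910 (0.0573), WT 4 h 918 (0.0570) or smn2 0 h 918 (0.0831), and against a fold of 1.5 (0.0542). PCC1 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.130) or WT 0 h 918 (0.0886). ECS1 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0656). BGL2 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0592), WT 0 h 918 (0.147), smn2 0 h 910 (0.0924) or smn2 0 h 918 (0.0929), and against a fold of 1.5 (0.0579). AT1G34400 lost its edgeR call at 0 h without intron reads (adjusted p = 0.111). FMO1 had a log2 value at 0 h of -3.60 without smn2 0 h 910. WRKY54 had a log2 value at 0 h of -3.79 without smn2 0 h 910. PCC1 had a log2 value at 0 h of -5.98 without smn2 0 h 910 and -3.56 without smn2 0 h 918. ECS1 had a log2 value at 0 h of -5.35 without smn2 0 h 910.

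Of 31 salicylic acid genes 5 were lower (DESeq2 8, 16 adjusted over the list alone, median -1.19, camera adjusted p = 2.29e-11, adjusted p = 0.544 with an estimated correlation). Within runs, on log2 CPM with a pseudocount of 2, a scale on which sizes cannot be compared with the fitted values, the list's median was -0.56 with 29 of 31 members lower (910) and -1.16 with 27 lower (918), and the medians at 4 h were 0.01 (910) and 0.13 (918). CCA1, a clock gene, had 45 CPM in WT and 79.2 CPM in smn2 in run 910, and 5.93 and 18.5 CPM in run 918. Root markers moved with them: their median was -0.87 over 19 genes, none past the edgeR threshold (4 at unadjusted p under 0.05, DESeq2 0, 0 adjusted over the list alone, camera adjusted p = 2.03e-05, adjusted p = 0.547 with an estimated correlation). Jasmonate genes had a median of -0.61, or -0.56 with zero-read members at their bound (edgeR 0 of 21, 6 at unadjusted p under 0.05, DESeq2 1 lower, 1 lower adjusted over the list alone, camera adjusted p = 1.23e-05, adjusted p = 0.547 with an estimated correlation). The flg22 markers had a median of -0.48 (edgeR 0 of 30, 10 at unadjusted p under 0.05, DESeq2 2 lower, 0 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.707 with an estimated correlation). Camalexin genes had -0.41 (edgeR 0 of 20, 3 at unadjusted p under 0.05, DESeq2 2 lower, 0 adjusted over the list alone, camera adjusted p = 0.0433, and 0.0694 with the run as a block, which is not called, adjusted p = 0.797 with an estimated correlation). Flg22 markers lost the camera call at 0 h without WT 0 h 918 (adjusted p = 0.617) or smn2 0 h 910 (0.811). Camalexin genes lost the camera call at 0 h without WT 0 h 918 (adjusted p = 0.618) or smn2 0 h 910 (0.880).

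Camera called 4 lists of non-coding genes higher in smn2 at 0 h, none of which passed with an estimated correlation. LncRNA genes rose in 4 of 103 cases (DESeq2 13, 17 adjusted over the list alone, median 0.51, camera adjusted p = 6.1e-07, adjusted p = 0.0948 with an estimated correlation, fry adjusted p = 0.00380). Of 46 snoRNA genes 0 passed by edgeR (16 at unadjusted p under 0.05, DESeq2 5 higher, 7 adjusted over the list alone, median 0.98, camera adjusted p = 8.66e-10, adjusted p = 0.628 with an estimated correlation). Of 13 snRNA genes 3 rose (4 adjusted over the list alone, median 0.96, camera adjusted p = 0.0105, adjusted p = 0.680 with an estimated correlation). Of 77 other ncRNA genes 4 rose (6 rose and 1 fell adjusted over the list alone, median 0.08, camera adjusted p = 0.0300, adjusted p = 0.547 with an estimated correlation). The 40 tRNA genes, not among the lists, had a median of -0.40. U6-1 rose by 5.57 ± 0.78, but it overlaps other loci and 10.2% of its reads were uniquely placed. The remaining lists were not called by camera: receptors and kinases (edgeR 0 of 12, 1 at unadjusted p under 0.05, DESeq2 0, adjusted p = 0.550), MAP kinases (SUMM2 higher by 1.35 ± 0.22, MPK11 lower at -2.49 ± 0.42, both also adjusted over the list alone, 0.165), NLR (2 of 28 higher, RPP1 by 1.4 ± 0.24, and 1 lower, also adjusted over the list alone, 0.810) and the RPS6 cluster (edgeR 0 of 7, 0 at unadjusted p under 0.05, DESeq2 0, 0.290). Nor were exosome and decay genes called, of which only HEN2 was lower (2 higher and 1 lower adjusted over the list alone, 0.673). With edgeR and DESeq2 calling 0 members and camera not calling the list, the others were ethylene (0.682, 0 at unadjusted p under 0.05), light harvesting (0.682, 0), auxin (0.943, 2), clock (0.864, 1), heat shock (0.212, 1), vascular (0.416, 1, and 1 higher adjusted over the list alone) and pseudogenes (0.416, 1). U6-1 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0592), WT 0 h 910 (0.103) or WT 0 h 918 (0.0856). SUMM2 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.144), WT 0 h 910 (0.0527), WT 0 h 918 (0.198), WT 4 h 910 (0.0585), WT 4 h 918 (0.0571), smn2 0 h 910 (0.0902), smn2 4 h 910 (0.0566) or smn2 4 h 918 (0.0548), and against a fold of 1.5 (0.129). MPK11 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.198), WT 0 h 918 (0.136), WT 4 h 910 (0.0601), WT 4 h 918 (0.0575), smn2 0 h 910 (0.101), smn2 0 h 918 (0.0963) or smn2 4 h 910 (0.0515), and against a fold of 1.5 (0.0665). RPP1 lost its edgeR call at 0 h without the other 4 libraries (adjusted p = 0.0976), WT 0 h 910 (0.2), WT 0 h 918 (0.194), WT 4 h 910 (0.0601), WT 4 h 918 (0.0571), smn2 0 h 910 (0.0743) or smn2 0 h 918 (0.0600), and against a fold of 1.5 (0.141). SnRNA genes lost the camera call at 0 h without WT 0 h 910 (adjusted p = 0.533) or smn2 0 h 918 (0.467). Other ncRNA genes lost the camera call at 0 h without smn2 0 h 910 (adjusted p = 0.0572). U6-1 had a log2 value at 0 h of 4.79 without WT 0 h 910, 6.42 without WT 0 h 918 and 4.96 without smn2 0 h 918. U6-1 had 0 reads left in WT at 0 h with uniquely placed reads, so its size there is not given.

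In all, 144 loci were higher and 53 lower in smn2 at 0 h, 143 and 53 of them at least 2-fold. The counts changed when 1 library was left out, also when it came from a 4 h group, which is not compared here. Such a fit keeps 1 library in a group and has less power. The changes therefore cannot show whether the counts rest on single libraries. The counts were 16 and 0 with only the 4 libraries at 0 h (edgeR, 1666 at unadjusted p under 0.05), 231 and 117 by DESeq2, 224 and 89 with the run as a block, 69 and 17 against a fold of 1.5, and 435 and 438 without the low-count filter.

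The same comparison was made after 4 h of flg22. AT4G08760 rose from 2.11 ± 0.0135 to 110.3 ± 28.1 CPM (n = 2), a log2 value of 5.70 ± 0.30, and AT1G34400 and EDA34 had 7.30 ± 0.53 (4.70 with exon reads alone) and 7.40 ± 0.71. RLP19, a receptor-like protein gene, rose by 4.05 ± 0.48. PCR1 (-3.26 ± 0.41), a metal resistance gene, and ECS1 (-3.21 ± 0.42) were lower, and AT2G06002, a non-coding RNA, had 0 reads in smn2 at 4 h, at least 14.1-fold lower; it lies on chromosome 2 at 2330776 to 2331479, in the window that holds HEN2. AT1G34400 lost its edgeR call at 4 h without intron reads (adjusted p = 0.279). EDA34 lost its edgeR call at 4 h without WT 4 h 910 (adjusted p = 0.107) or WT 4 h 918 (0.103). RLP19 lost its edgeR call at 4 h without WT 4 h 918 (adjusted p = 0.0531) or smn2 4 h 910 (0.113). PCR1 lost its edgeR call at 4 h without WT 4 h 910 (adjusted p = 0.107), WT 4 h 918 (0.129), smn2 4 h 910 (0.202) or smn2 4 h 918 (0.122). ECS1 lost its edgeR call at 4 h without WT 4 h 910 (adjusted p = 0.102), WT 4 h 918 (0.178), smn2 4 h 910 (0.185) or smn2 4 h 918 (0.188). AT2G06002 lost its edgeR call at 4 h without WT 0 h 910 (adjusted p = 0.0689), WT 0 h 918 (0.0637), WT 4 h 910 (0.223), WT 4 h 918 (0.178), smn2 4 h 910 (0.256) or smn2 4 h 918 (0.152), and against a fold of 1.5 (0.0615). AT4G08760 had a log2 value at 4 h of 4.41 with exon reads alone. AT1G34400 had a log2 value at 4 h of 6.63 without smn2 4 h 910. RLP19 had a log2 value at 4 h of 5.09 without WT 4 h 910 and 3.47 without WT 4 h 918.

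**Figure D3:**
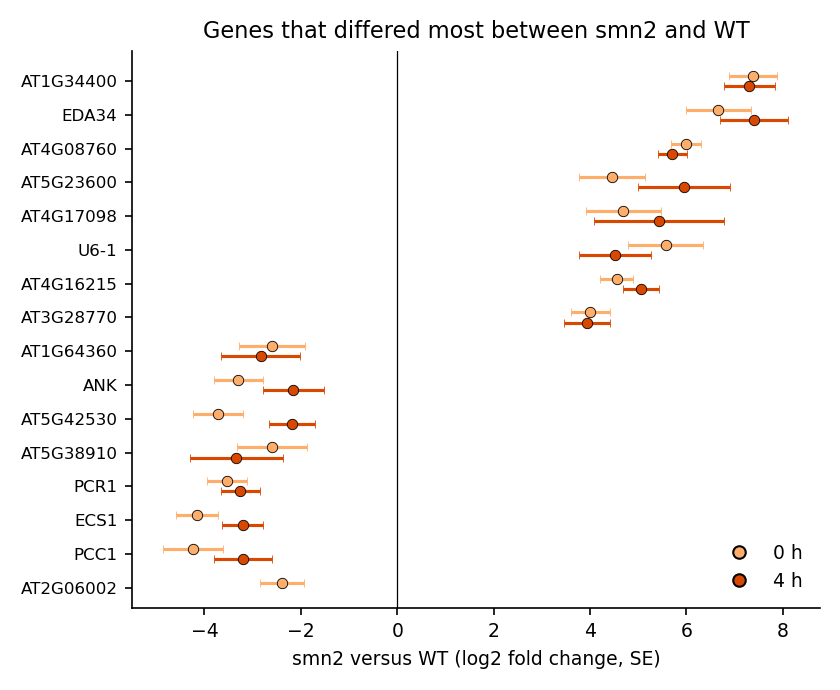
Log2 value of smn2 against WT (x axis, ± SE, n = 2 per group) at 0 h and 4 h for 16 genes. AT2G06002 had 0 reads in smn2 at 4 h and is drawn for 0 h only.

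The salicylic acid list had 0 of 31 members past the edgeR threshold at 4 h (6 at unadjusted p under 0.05, DESeq2 1 lower, 1 lower adjusted over the list alone, camera adjusted p = 0.574). The difference between 4 h and 0 h was tested as the interaction, where the list had a median of 0.74 and an adjusted p of 0.544 with an estimated correlation. Flg22 markers had a median of 0.42 (edgeR 0 of 30, 4 at unadjusted p under 0.05, DESeq2 1 higher, 1 higher adjusted over the list alone, camera adjusted p = 9.09e-06, adjusted p = 0.588 with an estimated correlation). Camalexin genes had 0.43 (edgeR 0 of 20, 0 at unadjusted p under 0.05, DESeq2 0, 0 adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.637 with an estimated correlation). Receptors and kinases had 0.30 (edgeR 0 of 12, 1 unadjusted, DESeq2 0, list alone 0, camera 0.0294, adjusted p = 0.695 with an estimated correlation), NLR genes 0.19 (0 of 28, 4 unadjusted, DESeq2 1 higher, list alone 1 higher, camera 0.0248, adjusted p = 0.636 with an estimated correlation) and heat shock genes -0.92 (0 of 13, 4 unadjusted, DESeq2 0, list alone 1 lower, camera 0.01, adjusted p = 0.588 with an estimated correlation). LncRNA genes rose in 2 of 103 cases (DESeq2 10, 11 adjusted over the list alone, median 0.48, camera adjusted p = 1.41e-06, adjusted p = 0.0948 with an estimated correlation). Other ncRNA genes had a median of 0.29, or 0.28 with zero-read members at their bound (1 of 77 lower, DESeq2 6 higher and 1 lower, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00713, adjusted p = 0.544 with an estimated correlation). Not called by camera were snoRNA (edgeR 0 of 46, 8 at unadjusted p under 0.05, DESeq2 2 higher, 0.131, and 0.000636 with the run as a block, which is called), snRNA (1 of 13 higher, 4 adjusted over the list alone, median 0.01, 0.153), and exosome (only HEN2 of 30 lower, 1 higher and 1 lower adjusted over the list alone, 0.682). By edgeR and DESeq2 0 members passed, and camera called none, of MAP kinases (camera adjusted p = 1 and 1 member at unadjusted p under 0.05, in this order also for the next), the RPS6 cluster (0.138, 0), jasmonate (0.577, 4), ethylene (0.973, 2), light harvesting (0.513, 0), auxin (0.645, 4), clock (0.761, 0), vascular (0.943, 1), pseudogenes (0.726, 0) and root markers (0.290, 1), whose median of -0.48 was -0.40 with zero-read members at their bound. Camalexin genes lost the camera call at 4 h without WT 4 h 918 (adjusted p = 0.490). Receptor and kinase genes lost the camera call at 4 h without WT 4 h 918 (adjusted p = 0.232) or smn2 4 h 910 (0.279). NLR genes lost the camera call at 4 h without WT 4 h 918 (adjusted p = 0.263) or smn2 4 h 910 (0.494). Heat shock genes lost the camera call at 4 h without WT 4 h 918 (adjusted p = 0.126) or smn2 4 h 918 (0.399). Other ncRNA genes lost the camera call at 4 h without WT 4 h 918 (adjusted p = 0.0514).

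**Figure D4:**
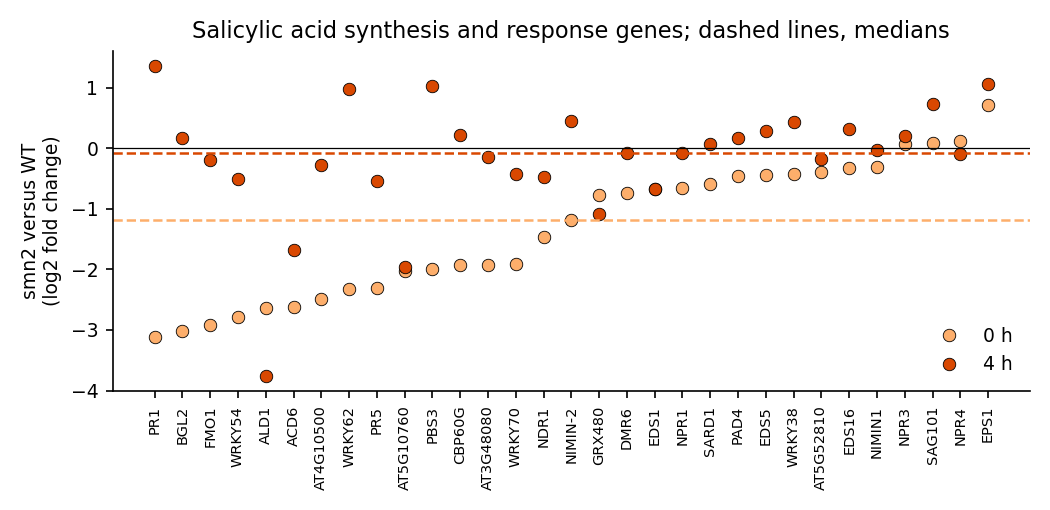
Log2 value of smn2 against WT for 31 salicylic acid genes at 0 h and 4 h, with dashed lines at the medians of -1.19 and -0.08. The value of ALD1 at 4 h rests on 1 read.

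In all, 55 loci were higher and 6 lower in smn2 at 4 h. Without 1 library they were 13 and 0 (WT 4 h, 910), 6 and 0 (WT 4 h, 918), 10 and 0 (smn2 4 h, 910) and 20 and 1 (smn2 4 h, 918), where edgeR counts of 0 stand beside 6 in the full fit. They were 135 and 18 by DESeq2, 108 higher with the run as a block, 23 and 3 against a fold of 1.5, 81 and 10 with only the 4 libraries at 4 h, and 339 and 141 without the low-count filter.

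The mean of both genotype effects used all 8 libraries. EDA34 (7.03 ± 0.49, 75.0% of reads uniquely placed), AT4G08760 (5.85 ± 0.22) and AT4G16215 (4.8 ± 0.25) were higher in smn2, and ECS1 (-3.68 ± 0.30), PCR1 (-3.39 ± 0.29) and ACD6 (-2.14 ± 0.25) lower. VSP1, a jasmonate-responsive gene, was lower, at -2.04 ± 0.35. GUT15, a non-coding RNA, rose by 1.34 ± 0.16. The lncRNA genes AT1G44125 (3.57 ± 0.30, 0.541% of reads uniquely placed) and AT1G79529 (3.29 ± 0.27) rose, and all 13 lncRNA genes called overlap another locus, so their reads cannot be assigned with certainty. VSP1 lost its edgeR call without WT 0 h 918 (adjusted p = 0.0805), WT 4 h 910 (0.0850), WT 4 h 918 (0.0608), smn2 4 h 910 (0.0980) or smn2 4 h 918 (0.0645), and against a fold of 1.5 (0.0670). EDA34 had a log2 value of 6.21 with exon reads alone. EDA34 had 0 reads left in WT at 0 h without WT 0 h 910, so its size there is not given. AT4G08760 had a log2 value of 5 with exon reads alone. AT4G16215 had 0 reads left in WT at 4 h with exon reads alone, so its size there is not given. ECS1 had a log2 value of -4.28 without smn2 0 h 910.

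LncRNA genes rose in 13 of 103 cases (23 adjusted over the list alone, median 0.45, camera adjusted p = 7.56e-09, adjusted p = 0.0948 with an estimated correlation, fry adjusted p = 0.00380). Of 46 snoRNA genes 4 rose (DESeq2 7, 11 adjusted over the list alone, median 0.61, camera adjusted p = 2.98e-06, adjusted p = 0.682 with an estimated correlation). Of 13 snRNA genes 4 rose, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0248, adjusted p = 0.707 with an estimated correlation). Of 77 other ncRNA genes 5 rose and 1 fell (DESeq2 12 and 1, 18 and 1 adjusted over the list alone, median 0.20, camera adjusted p = 0.00320, adjusted p = 0.544 with an estimated correlation). Of 31 salicylic acid genes 5 were lower (13 adjusted over the list alone, median -0.67, camera adjusted p = 9.81e-07, adjusted p = 0.547 with an estimated correlation). Jasmonate genes (1 of 21 lower, also adjusted over the list alone, median -0.39, camera adjusted p = 0.00182, adjusted p = 0.588 with an estimated correlation) and root markers (edgeR 0 of 19, 5 at unadjusted p under 0.05, DESeq2 0, 0 adjusted over the list alone, median -0.62, camera adjusted p = 0.00265, adjusted p = 0.588 with an estimated correlation) had lower medians. Not called by camera were MAP kinases (1 of 18 higher and 1 lower, 0.439), NLR (2 of 28 higher and 1 lower, 0.176), exosome (2 of 30 higher and 1 lower, 0.943) and vascular markers (1 of 11 higher, CESA4, which overlaps another gene, 0.629), the counts being the same adjusted over the list alone. By edgeR and DESeq2 0 members passed, and camera called none, of flg22 markers (camera adjusted p = 1 and 3 members at unadjusted p under 0.05, in this order also for the next), receptors and kinases (0.634, 1), the RPS6 cluster (0.0843, 0), camalexin (0.928, 0), ethylene (0.855, 1), light harvesting (0.551, 1), auxin (0.855, 3), clock (0.810, 1), heat shock (0.682, 0) and pseudogenes (0.423, 0). Over all comparisons, the median, the mean and the camera direction of a list differed in sign in 14 list tests, 0 of them called by camera (lowest adjusted p = 0.645). They were NLR in smn2, exosome at 4 h and in the mean, ethylene at 4 h, auxin at 4 h and in the mean, clock at 0 h and in the mean, vascular at 4 h, snRNA in smn2, lncRNA in WT, smn2 and the interaction, and other ncRNA in the interaction. CESA4 lost its edgeR call without intron reads (adjusted p = 0.263), WT 0 h 910 (0.0967), WT 0 h 918 (0.108), WT 4 h 910 (0.135), WT 4 h 918 (0.0974), smn2 0 h 910 (0.0761), smn2 4 h 910 (0.102) or smn2 4 h 918 (0.115), and against a fold of 1.5 (1). SnRNA genes lost the camera call without WT 0 h 910 (adjusted p = 0.312), WT 4 h 910 (0.161), smn2 0 h 918 (0.369) or smn2 4 h 918 (0.0996). Jasmonate genes lost the camera call without smn2 0 h 910 (adjusted p = 0.0621).

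In all, 282 loci were higher and 71 lower in smn2 over both times. Without 1 library they were 180 and 50 (WT 0 h, 910), 150 and 37 (WT 0 h, 918), 135 and 27 (WT 4 h, 910), 116 and 25 (WT 4 h, 918), 231 and 135 (smn2 0 h, 910), 141 and 36 (smn2 4 h, 910) and 159 and 20 (smn2 4 h, 918). The lower count was 140 by DESeq2 and 126 with the run as a block; 107 and 16 loci passed against a fold of 1.5, and 666 and 489 without the low-count filter. The genotype effects at 0 h and 4 h, which share no library, correlated with r = 0.410 (rho 0.293) across genes; 46 loci were higher at both times (0.403 for independent lists), 5 lower at both (0.0162) and 0 opposite. Without 1 library r was 0.345 (WT 0 h, 910), 0.342 (WT 0 h, 918), 0.303 (WT 4 h, 910), 0.320 (WT 4 h, 918), 0.265 (smn2 0 h, 910), 0.328 (smn2 0 h, 918), 0.307 (smn2 4 h, 910) and 0.304 (smn2 4 h, 918).

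Called genes were counted in windows along the genome. In the window holding HEN2 (chromosome 2, 2000001 to 3000000), 2 of 40 tested loci were called in the mean comparison, HEN2 itself and AT2G06002. This window therefore does not test for differences linked to HEN2. AT2G06002 had 7.21 CPM in WT and 1.45 CPM in smn2 at 0 h, and 0 reads in smn2 at 4 h, so its mean size is not given. In 1 of 122 windows, chromosome 3 from 16000001 to 17000000, 12 of 108 loci were called, 11 higher and 1 lower (exact test, adjusted p = 6.8e-05). They include the NLR gene RPP1 (1.39 ± 0.17, 67.1% of reads uniquely placed) and AT3G45420 (3.34 ± 0.17), chosen after its value was seen. GRIK1 and AT3G45242, both among the called loci, have the same coordinates (16570478 to 16573762). The exact test treats them as independent, although the same reads can count for both. With uniquely placed reads 10 of 106 loci in the window were called (exact test, adjusted p = 0.00322). The window was no longer called without WT 4 h 910 (exact test, adjusted p = 0.703), WT 4 h 918 (0.152), smn2 0 h 910 (0.136), smn2 4 h 910 (0.683) or smn2 4 h 918 (0.444), and a second window was called without smn2 0 h 918. No window was called at 0 h or 4 h alone by the exact test (lowest adjusted p 0.569 and 0.836).

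The series title names regions degraded through SMN2, so reads outside exons were compared. GAPCP-1, a plastid glycolysis gene that overlaps AT1G79529, had 9.07% ± 2 and 3.78% ± 0.356 of its reads outside exons in WT and 59.4% ± 0.621 and 52.0% ± 0.140 in smn2, at 0 h and 4 h (SD, n = 2). RECQ4A, a DNA helicase gene, had 2.2% ± 1.72 and 0.746% ± 1.06 in WT and 48.1% ± 13.8 and 44.4% ± 3.90 in smn2. ILA had 1.67% ± 0.0688 in WT and 18% ± 1.41 in smn2 at 0 h, and CA1, a carbonic anhydrase gene, 0.346% ± 0.261 and 9.08% ± 1.13. These genes were chosen after their values were seen. Over both times, limma called 28 of 2762 genes with a higher intron to exon ratio in smn2 and 1 with a lower one, PP2-B10 (35 and 3 with the run as a block), with log2 ratios of 5.51 ± 0.46 for RECQ4A and 4.01 ± 0.30 for GAPCP-1. The lower ratio of PP2-B10 rests on 0 intron reads in smn2 at 0 h, while its shares at 4 h were 39.2% in WT and 38.0% in smn2. The calls were 13 higher and 1 lower at 0 h, 7 and 1 at 4 h, and 0 and 0 for the difference (limma, 124 at unadjusted p under 0.05). Without smn2 0 h 910 the higher count was 18. Of the 28 genes, 7 were also called higher in gene reads, which include the intron reads, and 5 overlap another locus. Over all loci with exons, 1.86% to 2.03% of reads lay outside exons in WT libraries and 2.3% to 2.56% in smn2 libraries.

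**Figure D5:**
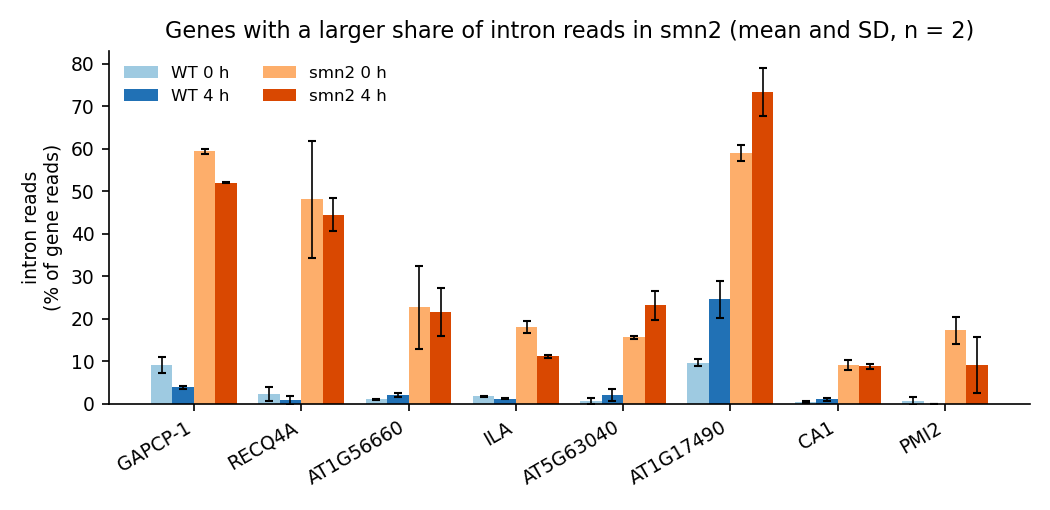
Share of reads outside exons (%, mean and SD of 2 libraries) in each group for 8 of the genes called. GAPCP-1 rose from 9.07% in WT to 59.4% in smn2 at 0 h.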

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

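The list tests below were fixed before the data were seen, and the root marker test of the salicylic acid pattern was chosen after the result was seen. Each value is the camera adjusted p of the difference between the 4 h changes, smn2 minus WT. It drew attention because a list's response differed between the genotypes by a test of the difference. With an estimated correlation none of the 8 lists passed, as none of the 126 list tests did, and by edgeR no single member did. At unadjusted p under 0.05 stood 9 salicylic acid, 11 flg22, 5 camalexin, 4 snoRNA, 2 jasmonate, 1 heat shock, 1 receptor or kinase and 2 root marker genes, and DESeq2 called 1 in each of the salicylic acid, flg22 and camalexin lists and 0 in the others. Salicylic acid genes had a median difference of 0.74 (2.68e-10, and 0.544 with an estimated correlation), with 27 of 31 members above 0 and 5 higher adjusted over the list alone. Flg22 markers had 0.93 (2.03e-08, and 0.547), with 24 of 30 above 0 and 6 higher adjusted over the list alone. Camalexin genes had 0.66 (3.81e-06, and 0.588), with 17 of 20 above 0 and 1 higher adjusted over the list alone. SnoRNA genes had -0.45 (0.000100, and 0.729), with 37 of 46 below 0. Jasmonate genes had 0.50 (0.000829, and 0.588), with 18 of 21 above 0. Heat shock genes had -1.34 (0.00110, and 0.547), with 12 of 13 below 0. Receptor and kinase genes had 0.43 (0.00915, and 0.670), with 10 of 12 above 0. Root markers had 0.40 (0.0248, and 0.637), with 14 of 19 above 0. Flg22 markers lost the camera call without smn2 0 h 910 (adjusted p = 0.0679). SnoRNA genes lost the camera call without WT 0 h 910 (adjusted p = 0.555), WT 4 h 918 (0.0543), smn2 0 h 918 (0.581) or smn2 4 h 910 (0.698). Jasmonate genes lost the camera call without WT 0 h 918 (adjusted p = 0.0560) or smn2 0 h 910 (0.112). Receptor and kinase genes lost the camera call without WT 0 h 918 (adjusted p = 0.498), WT 4 h 918 (0.0594), smn2 0 h 910 (0.407) or smn2 4 h 910 (0.0766). Root markers lost the camera call without WT 0 h 910 (adjusted p = 0.194), WT 4 h 910 (0.309), smn2 0 h 918 (0.482) or smn2 4 h 910 (0.431).

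The salicylic acid difference follows from lower values in smn2 at 0 h, where the median was -1.19, against -0.08 at 4 h. A single high WT library would have brought the median near 0 when left out, but it was -1.02 without WT 0 h 918 and -1.4 without WT 0 h 910. A larger share of root in smn2 seedlings would have raised root markers, whose median was -0.87 (-1.05 to -0.55, 17 of 19 below 0). The lower markers speak only to a larger share. Other differences in tissue make-up, a smaller share of root among them, were not tested and stay open. Collection at another time of day may add to the pattern: the clock genes' median absolute change of 0.313 lay at percentile 94.5 of 10000 random lists, which leaves this open, as does a difference due to the genotype itself, which was not tested apart from these.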

How the results depend on the processing

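Exon reads, fits without ribosomal and mitochondrial genes and the alternatives for windows and intron shares were tests chosen after the result was seen. Of 98 values of named genes in the edgeR fit none changed sign in the settings run, and 60 kept their side of the threshold in each of the 15 to 18 settings in which they were tested, and the others gave 148 weaker and 7 stronger values. Of the 50 list calls 30 held without each library, and 18 of the 76 lists not called were called without at least 1 library. By DESeq2, smn2 against WT had 231 loci higher and 117 lower at 0 h and 135 and 18 at 4 h, the interaction 25 and 3, and the mean 140 lower. Without the low-count filter, 2117 were lower at 4 h in WT, 435 higher and 438 lower for genotype at 0 h, 339 and 141 at 4 h, 148 and 37 for the interaction, and 666 and 489 for the mean. Loci higher in smn2 thereby went from 73.1% of calls to 49.8%, no longer the majority, at 0 h and from 79.9% to 57.7% in the mean. The lowest edgeR adjusted p in the mean was then 1.3e-168, against 4.31e-06 with the filter. Counts of the unfiltered fit therefore cannot be set beside the others on equal terms. With only the 4 libraries compared, 16 were higher and 0 lower at 0 h by edgeR, and 81 higher and 10 lower at 4 h. Against a fold of 1.5 the counts were 993 and 544 (WT), 1388 and 680 (smn2), 69 and 17 (0 h), 23 and 3 (4 h) and 107 and 16 (mean). Of 126 list tests 50 were called by camera, 0 with an estimated correlation and 10 by fry. The estimated correlation also left out the flg22 markers in smn2, of which 24 of 30 rose at 4 h by edgeR, so it could not decide between lists. With a mean count of at least 20 the correlation of 4 h changes was 0.866 and that of genotype effects 0.437. With the replicate block, genotype counts were 224 and 89 at 0 h, 108 higher at 4 h and 126 lower in the mean, and the interaction stayed at 0 and 0. The block changed 4 camera list calls, given with their lists, ended 5 of the 10 fry calls and changed none of the 98 named gene calls.

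Leaving out 1 library gave ranges of 884 to 2143 higher and 468 to 1463 lower (WT), 1469 to 2370 and 600 to 1649 (smn2), 17 to 107 and 3 to 76 (genotype, 0 h), 6 to 69 and 0 to 9 (4 h), and 116 to 274 and 20 to 135 (mean). The interaction stayed at 0 and 0 by edgeR. List calls ranged from 44 to 53, the correlation of 4 h changes from 0.667 to 0.774, that of genotype effects from 0.265 to 0.345, called windows from 0 to 2 and intron ratio calls from 18 to 34. The leave-out fits filtered the loci anew and tested 20030 to 20353 of them, against 19649 in the full fit. Their correlations, all below those of the full fit, therefore cover other sets of genes and groups of 1 library. The cause of the ranges was not tested. Counts with size factors of DESeq2, uniquely placed reads, exon reads, a mean count of at least 20, or without ribosomal and mitochondrial genes stayed within 1.5 times. Depth limits the weakly expressed genes: 3 counts correspond to 0.161 to 0.488 CPM.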

Other observations

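The tests of ribosomal share, of the genes beside called lncRNA genes and all intron ratio tests were chosen after the result was seen. MicroRNA precursor genes were not among the lists: in the mean of both times MIR156c was higher in smn2 by 2.05 ± 0.23 and MIR172a by 1.99 ± 0.38, and 2 of 29 tested miRNA genes were higher. Both were chosen after their values were seen. CCA1, a clock gene peaking at dawn, had 45 CPM (910) and 5.93 CPM (918) in WT at 0 h and 79.2 and 18.5 CPM in smn2 at 0 h. TOC1, a clock gene peaking in the evening, had 14.9 and 73.0 CPM in WT and 17.2 and 59.3 CPM in smn2 at 0 h, so both differed more between runs than between genotypes at 0 h. MIR172a lost its edgeR call without WT 0 h 910 (adjusted p = 0.0682), WT 0 h 918 (0.117), WT 4 h 910 (0.121), WT 4 h 918 (0.133), smn2 0 h 910 (0.0887), smn2 4 h 910 (0.0610) or smn2 4 h 918 (0.137), and against a fold of 1.5 (0.118).

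In the authors' deposited table, 390 loci were higher and 200 lower at 4 h in WT at an FDR under 0.05, and 580 of these 590 were also called by edgeR. For smn2 at 4 h the authors' deposited table gave 666 and 269, of which 916 were also called. For genotype it gave 24 and 13 at 0 h (32 also called) and 20 and 4 at 4 h (21 also called). All shared calls had the same direction. In that table FRK1 had signed folds at 4 h of 78.0 in WT and 235 in smn2. HEN2 had signed folds of -3.37 and -4 in the authors' deposited table, each at an FDR of 1.

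Camera called snRNA, snoRNA and lncRNA genes higher in smn2 in the mean of both times (adjusted p = 0.707, 0.682 and 0.0948 with an estimated correlation), with a median of 0.525 over 162 genes, of which edgeR called 21; the medians at 0 h and 4 h were 0.96 and 0.01 for snRNA, 0.98 and 0.36 for snoRNA, and 0.51 and 0.48 for lncRNA. More RNA without poly(A) tails in the smn2 libraries would have raised the share of 4 ribosomal RNA loci, yet the highest of 4 log2 ratios was 0.00073 and 40 tRNA genes had a median of -0.31. Only 101 of the 162 genes had enough uniquely placed reads to be tested with them. Their median was 0.546 (0.387 to 0.763) with such reads and 0.527 with total reads, so shared reads did not account for the rise in these genes. For the rest of the 162 genes shared reads could not be tested and stay open. Of the 21 genes called 15 were tested with uniquely placed reads and 13 were called. Spill in proportion to all reads of an overlapping coding gene would give pairs of equal size. Over 90 pairs the coding gene instead lay lower by a median log2 of -0.33 (-0.68 to -0.16). Spill from only part of a coding gene, such as an intron, could give the lncRNA gene a larger change, so the pairs cannot decide this. Among 14 coding genes beside the 13 called lncRNA genes 5 were called higher. Spill therefore stays open, as does a difference due to the genotype, which was not tested apart.

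A larger share of reads outside exons was called by limma for 28 genes in smn2. More unspliced RNA or DNA as a whole may add to this, since the uncentred median over 2762 genes was 0.246 (0.224 to 0.268), and its part in the called genes stays open. A rise alike in all genes would give those called at 0 h the common change in the other libraries, at 4 h, but the 13 genes had a median of 3.24 there (2.48 to 3.64) against 0.218 (0.189 to 0.244) over all genes. With uniquely placed reads 33 genes were called higher, including all 28. Of 34 divisions of the 8 libraries into 4 and 4, 1 reached the 38 genes of the real one, namely itself, and the highest other had 4. The division by time was left out because time was already fitted. Of the divisions, 17 held 2 libraries of each run in each part, the real one among them. In the others the genotype difference stayed in the spread between libraries and lowered their counts, so they do not measure chance alone. Reads ending in introns, overlapping antisense RNA and altered splicing were not told apart and stay open.

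The same divisions were made for gene reads. With time and division fitted by edgeR, 1 of 34 had at least the 357 loci of the real one, which was itself, and the highest other, the division by run, had 6. Here too the genotype difference stayed in the spread of the other divisions, so their low counts do not measure chance alone. The window on chromosome 3 was tested for technical explanations first. After the results were seen, the intron pattern replaced it among those weighed, so the choice of patterns was made with outcomes known. Outcomes of those window tests are not given here, so no conclusion on the window is drawn from them.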
